A study of Litchi chinensis with 12 samples.

How the data were processed

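Total RNA from leaves of the lychee genotypes named GW and SFZ was sequenced after inoculation with P. litchii or after mock inoculation with sterile water, with 3 libraries in each of the 4 groups. RNA was extracted with TRIzol, treated with DNase, and made into libraries with a NEBNext Ultra RNA kit for Illumina sequencing, per the labels' protocols. The deposited tables held, per the file headers, raw counts of reads per gene for each of the 12 libraries and, separately, FPKM values for the same libraries, with gene coordinates and a description of most genes. The submitters' processing notes name STAR, Picard, SAMtools 0.1.18 and HTSeq 0.5.4, without saying which step each one served. The genome build, the annotation release and the strand setting of the counting were not given in the sources used here, so coordinates are printed as the deposited tables give them. Each FPKM value that the authors deposited equalled the count divided by gene length and library total within a ratio of 0.996 to 1, so FPKM was not an independent measurement and served only as an alternative scale.

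The count table covered 33296 genes on 15 chromosomes. Of these, 1400 carried identifiers of genes added to the annotation, 3588 had no description, and 16528 had no description or one that named no function. In all libraries 7271 genes had 0 counts. Totals per library ran from 11091304 to 13659374 counts. Pairs of libraries of the same group differed by more than counting noise, with a chi-square per gene of 1.89 to 6.16, so no library was a copy of another and each counted as 1 replicate. Groups were taken from the sample titles. Nothing in the labels says that libraries came from separate trees or plants.

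Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed the filterByExpr rule, which left 19088, and library sizes were scaled with TMM factors, which ran from 0.838 to 1.13. A single quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, so that the groups shared the estimate of spread. The common biological coefficient of variation was 0.0535. Each comparison was a contrast of that model: inoculated against mock in GW, inoculated against mock in SFZ, the difference between these responses (interaction), and SFZ against GW after mock and after inoculation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Printed log2 fold changes carry the standard error implied by the quasi-likelihood F statistic. It is the fold change over the root of F, and can understate the error of large folds from groups near 0 counts. Levels are CPM, counts scaled to a common library total, on TMM-scaled libraries, as mean and SD over 3 libraries. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts summed over the group, which equals 0.0771 CPM in mock GW, 0.0983 CPM in inoculated GW, 0.0697 CPM in mock SFZ and 0.073 CPM in inoculated SFZ. Where a group had 1 to 3 counts, the ratio is given with the 95% exact Poisson interval of the lower group's count. Floors and intervals cover counting error only.

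Before the data were examined, 35 lists of genes were fixed as patterns of words in gene descriptions, among them pathogenesis-related (PR) proteins, WRKY, NAC and ERF transcription factors, hormone pathways, peroxidases, photosynthesis, the cytosolic ribosome, and markers of xylem, phloem, epidermis, guard cells, dividing cells and organelle transcripts. The lists held 1941 tested genes, of which 45 were in more than 1 list. A list was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, first with a preset correlation of 0.01 between genes and then with the correlation estimated from the data, and with fry. Adjustment ran over the 34 lists with at least 5 tested members within each contrast. The organelle list also took in nuclear genes described by names such as psbY. In the salicylic acid list, some members were matched through names of related resistance genes.

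Named genes were chosen by a rule fixed in advance. In each response, in the interaction and in the mock comparison, the rule took the 5 largest positive and 5 largest negative fold changes among called genes with at least 5 CPM in the higher group, separate replicates (not asked of the interaction) and an informative description. It also took, for up to 20 lists in each response, the called member with the smallest p that met the same conditions. The rule gave 69 genes. After the results were seen, further examples were added, namely the member of each called list with the next smallest p in each response and the 2 with the smallest p in the interaction. Genes of the circadian clock and genes detected in 1 genotype only, in the closing section, were also chosen after values were seen.

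On counts simulated for the 19088 tested genes with 200 genes changed, the GW comparison recovered 28% of genes changed 1.25-fold, 60% at 1.5-fold, 68% at 2-fold and 98% at 4-fold, with 9 false calls among 136. For the interaction the shares were 8%, 48%, 56% and 88%, with 6 false calls among 106. In the comparison of inoculated leaves they were 36%, 58%, 72% and 98%, with 12 false calls among 144. The comparisons simulated without change gave 0 calls in edgeR. In simulated data with 1 list shifted by 0.5 on the log2 scale, that list ranked 1 by p and 0 others were called. Genes were drawn independently and few were changed, whereas most tested genes were called in each 2-group comparison of the real data. These simulations therefore do not show how camera performs with correlated genes, or the tests and scaling when most genes change.

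Alternatives were DESeq2 1.42.0 in place of edgeR, RLE in place of TMM factors, no filter on low counts, a filter of 1 CPM in 3 libraries, a log2 fold change of at least 1, only the libraries of the groups compared, limma on log2 of FPKM plus a pseudocount of 1 or 0.1, the replicate number as a block, and each library left out in turn. Library totals as the only scaling was added after the data were seen. This last setting moved the median log2 fold change of all genes by -0.29 in GW, -0.15 in SFZ, 0.15 in the interaction, 0.11 in mock leaves and 0.26 in inoculated leaves, while RLE factors moved none of them by more than 0.08. Reads of the pathogen itself were not analysed here.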

Results

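Leaves of the lychee (Litchi chinensis) genotypes named GW and SFZ were inoculated with P. litchii, the oomycete that causes lychee downy blight, or treated with sterile water as a mock, and their RNA was sequenced. Each of the 4 groups had 3 libraries, 12 in all. Mock GW libraries held 12050350, 12635063 and 12798951 counts, and inoculated GW libraries held 12440082, 12527420 and 11091304. Mock SFZ libraries held 12636325, 12765950 and 13055080 counts, and inoculated SFZ libraries held 13659374, 13581288 and 13361052. Between 20589 and 22182 genes had a count in a library. The comparisons asked how the transcripts of each genotype changed under downy blight stress, whether these responses differed, and how the genotypes differed under each treatment. The interval between inoculation and sampling was not given in the sources used here.

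Libraries of the same group correlated at 0.988 to 0.992 across the 19088 tested genes (Pearson's r of log2 CPM), and libraries of different groups at 0.739 to 0.867. The leading principal components carried 46.6% and 42.5% of the variance. On the first component, inoculated GW libraries lay opposite mock SFZ libraries, and on the second mock GW lay opposite inoculated SFZ. No statement in the labels says that libraries came from separate plants, so the p-values measure only the spread between these samples, which may be technical. Members of multigene families, overlapping genes and antisense partners can share or exchange reads, and their values are uncertain because the strand setting of the counting was not given in the sources used here. The build behind the printed coordinates was likewise not given in the sources used here.

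**Figure D1:**
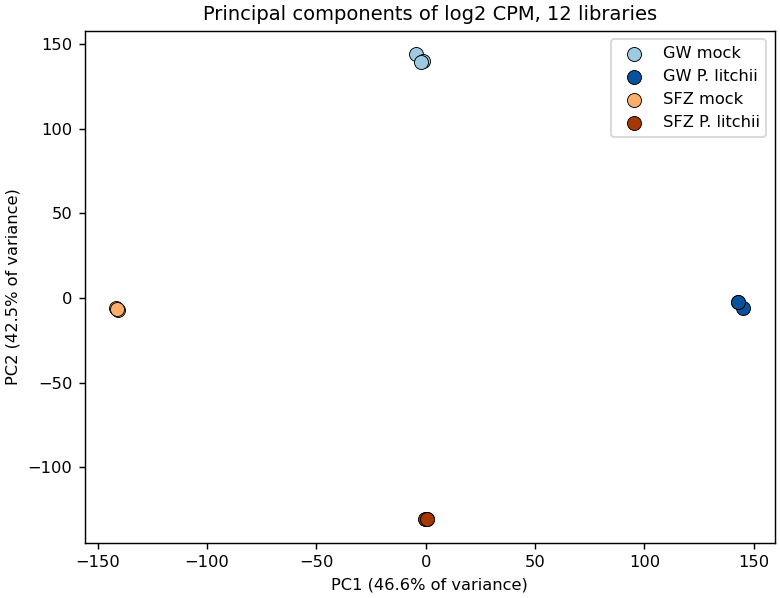
Principal components of log2 CPM of the 19088 tested genes, with 1 point per library and 1 colour per group; the axes are component scores, with 46.6% and 42.5% of the variance. The 3 libraries of each group lie together.

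In GW leaves, a thaumatin-like protein (LITCHI009151, chromosome 7, 22987195 to 22988421), of a family of antifungal PR proteins, rose from 0.642 ± 0.23 to 1349 ± 40.5 CPM (SD, n = 3), a log2 fold change of 11.02 ± 0.09 (SE, edgeR quasi-likelihood adjusted p = 6.02e-38). Peroxidase A2 (LITCHI024182, chromosome 13, 12615687 to 12639328), a secreted enzyme that uses hydrogen peroxide, rose from 1.94 ± 0.629 to 2163 ± 38.3 CPM (log2 10.12 ± 0.08, edgeR adjusted p = 5.85e-38). For both genes the mock level was near 0, so the SE can understate the error of the fold. Laccase 7 (LITCHI018291, chromosome 15, 4348333 to 4351861), a copper oxidase of a family that polymerises lignin, had 0 counts in mock GW leaves and 457 ± 19.5 CPM after inoculation, at least 5924-fold higher. Rubisco activase (LITCHI027700, chromosome 3, 26741723 to 26744714), which keeps the carbon-fixing enzyme active, fell from 1429.6 ± 39.9 to 150.1 ± 6.23 CPM (log2 -3.25 ± 0.04, edgeR adjusted p = 5.03e-32). In all, 6227 genes rose and 7215 fell in GW (edgeR adjusted p under 0.05), of which 2784 and 3732 changed at least 2-fold. With library totals as the only scaling, chosen after the data were seen, 4441 rose and 9494 fell. With RLE factors 6687 rose and 6713 fell, and with DESeq2 6565 rose and 6408 fell, so the balance of rises and falls depended on the setting.

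Of 75 tested PR protein genes, which include chitinases, thaumatins and lipid-transfer proteins, 44 rose, 15 fell and 16 did not pass in GW. Their median log2 fold change was 1.49, or 1.18 with genes at 0 counts set to their bound (camera adjusted p = 5.45e-06, adjusted p = 0.0726 with an estimated correlation). The gene described as pathogenesis-related protein P2 (LITCHI003626) rose from 22.4 ± 1.7 to 2519 ± 60.2 CPM (n = 3). A non-specific lipid-transfer protein (LITCHI031080) went from 0 counts to 65.3 ± 0.961 CPM, at least 847-fold. Among 44 antioxidant and detoxification genes 26 rose and 13 fell, with a median of 0.41, or 0.34 with bounds (camera adjusted p = 0.0325, adjusted p = 0.368 with an estimated correlation). The glutathione transferase genes LITCHI023121 and LITCHI020167 rose by 3.75 ± 0.07 and 1.86 ± 0.05 (log2, SE). Peroxidases and NADPH oxidases gave 21 rises and 13 falls among 41, and did not pass as a list (camera adjusted p = 0.0693).

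Of 22 jasmonate genes 15 rose and 4 fell in GW, with a median of 0.63 (camera adjusted p = 0.0325, adjusted p = 0.114 with an estimated correlation). A gene described only as lipoxygenase (LITCHI004066) rose from 218 ± 22.4 to 829 ± 10.2 CPM (n = 3), and its part in jasmonate synthesis was not tested. By contrast, a chloroplast 13S-lipoxygenase (LITCHI024086) fell from 211 ± 9.55 to 47.3 ± 3.45 CPM. Another gene of that description (LITCHI024090) ran from 33.8 to 44.2 CPM in mock and from 31.6 to 42.3 CPM in inoculated GW libraries. Allene oxide synthase 3 (LITCHI001739) had 0 counts after mock and 44.8 ± 3.09 CPM after inoculation, at least 581-fold higher. Of 25 ethylene genes 15 rose and 5 fell, with a median of 0.64 (camera adjusted p = 0.0325, adjusted p = 0.126 with an estimated correlation). An aminocyclopropane-carboxylate synthase (LITCHI022037), of the committed step of ethylene synthesis, rose from 2.74 ± 0.83 to 81.7 ± 4.55 CPM, and ethylene receptor 2 (LITCHI015371) from 45.6 ± 0.83 to 556 ± 3.42 CPM. Among 53 ERF transcription factors, the ethylene-responsive class, 29 rose and 15 fell, with a median of 0.51 (camera adjusted p = 0.0419, adjusted p = 0.22 with an estimated correlation). RAP2-3 (LITCHI014444) reached 1932 ± 61.8 CPM from 54.7 ± 5.27, and ERF114 (LITCHI020245) reached 287 ± 3.58 CPM from 1.42 ± 0.411. The WRKY and NAC lists did not pass in GW (camera adjusted p = 0.066 and 0.069). WRKY factors gave 17 rises and 12 falls, or 17 and 18 with library totals only, and NAC factors 21 and 8. Within these lists WRKY 75 (LITCHI020315) rose by 5.78 ± 0.11 and NAC 72 (LITCHI013207) by 2.12 ± 0.04 (log2, SE).

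Of 85 genes for cytosolic ribosomal proteins 76 rose and 2 fell in GW, with a median of 0.91, or 0.9 with bounds (camera adjusted p = 2.05e-15, adjusted p = 0.107 with an estimated correlation). The 40S protein S4-3 (LITCHI018123) rose from 122 ± 5.17 to 328 ± 12.9 CPM and the 60S protein L10 (LITCHI031025) from 552 ± 20.8 to 1238 ± 35.1 CPM (n = 3). Of 18 genes for folding and translocation in the endoplasmic reticulum 14 rose and 2 fell, with a median of 0.7 (camera adjusted p = 0.00164, adjusted p = 0.0726 with an estimated correlation). They included luminal-binding protein 5 (LITCHI012388), an Hsp70 chaperone of this compartment, at log2 2.49 ± 0.06, and the translocon subunit Sec61 gamma (LITCHI020758) at 1.38 ± 0.05. Among 96 heat shock genes 47 rose and 21 fell, with a median of 0.23, a balance that turned to 32 rises and 38 falls and a median of -0.04 with library totals only (camera adjusted p = 0.0325, adjusted p = 0.0726 with an estimated correlation). An HSP20-like chaperone (LITCHI023051) rose from 1.99 ± 0.473 to 221 ± 8.8 CPM.

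Of 37 photosynthesis genes tested in GW, 31 fell, 2 rose and 4 did not pass, with a median of -1.82, or -1.77 with bounds (camera adjusted p = 4.87e-09, adjusted p = 0.0726 with an estimated correlation). The antenna protein CP26 (LITCHI012016) fell from 1392 ± 4.76 to 249.6 ± 10.3 CPM (n = 3). Of 16 xylem markers 11 fell and 1 rose, with a median of -4.06, or -2.9 with bounds (camera adjusted p = 0.00955, adjusted p = 0.0726 with an estimated correlation). Among them the secondary-wall cellulose synthase CesA7 (LITCHI016041) fell from 25.8 ± 3.7 to 1.96 ± 0.704 CPM and the xylan enzyme IRX7 (LITCHI024592) from 86.1 ± 6.63 to 26.5 ± 3.19 CPM. Of 50 subtilases and other proteases 33 fell and 10 rose, with a median of -0.88, or -0.82 with bounds (camera adjusted p = 0.0325, adjusted p = 0.0864 with an estimated correlation). The subtilase SBT1.3 (LITCHI009223) fell by 3.95 ± 0.14 on the log2 scale, and a copy of SBT1.1 (LITCHI012243) dropped from 5.27 ± 0.464 CPM to 0 counts, at least 53-fold lower. A GDSL esterase (LITCHI016421) went from 105 ± 21.6 CPM to 3 counts in all, a ratio of 1070.0 (95% interval 366 to 5188).

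Several single genes stood out by size in GW. A protease inhibitor (LITCHI015389) had 0 counts after mock and was at least 2977-fold higher after inoculation, and a berberine bridge enzyme-like gene (LITCHI023024) at least 1648-fold. Sugar transport protein 13 (LITCHI014765), a hexose importer, rose from 9.85 ± 0.689 to 659.8 ± 15.7 CPM, and the calcium-signalling kinase CIPK2 (LITCHI027467) from 13.7 ± 1.28 to 661 ± 26 CPM (n = 3). An aspartyl protease (LITCHI006406) fell from 141 ± 22 to 0.56 ± 0.16 CPM. Among markers of other leaf cell types, 13 of 24 epidermis genes fell and 8 rose (camera adjusted p = 0.128), and 7 of 13 phloem genes rose and 2 fell (camera adjusted p = 0.233, with a median of 0.25 that turned to -0.05 with library totals only). Of 4 guard cell genes 2 fell and 0 rose. Organelle transcripts gave 10 falls and 2 rises among 19 (camera adjusted p = 0.177). Medians of several lists in GW were smaller in other settings. With library totals only they were 0.12 for antioxidant genes (20 rises and 14 falls), 0.21 for ERF factors, 0.35 for ethylene, 0.34 for jasmonate and 0.41 for folding genes. With limma on log2(FPKM + 1) they were 0.04, 0.14, 0.29, 0.23 and 0.39 for the same lists, 0.40 for PR proteins, 0.59 for the cytosolic ribosome and -1 for xylem markers. For each list of this comparison that passed, the counts adjusted over the list alone were the same as those over all genes. No list kept its call with an estimated correlation.

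**Figure D2:**
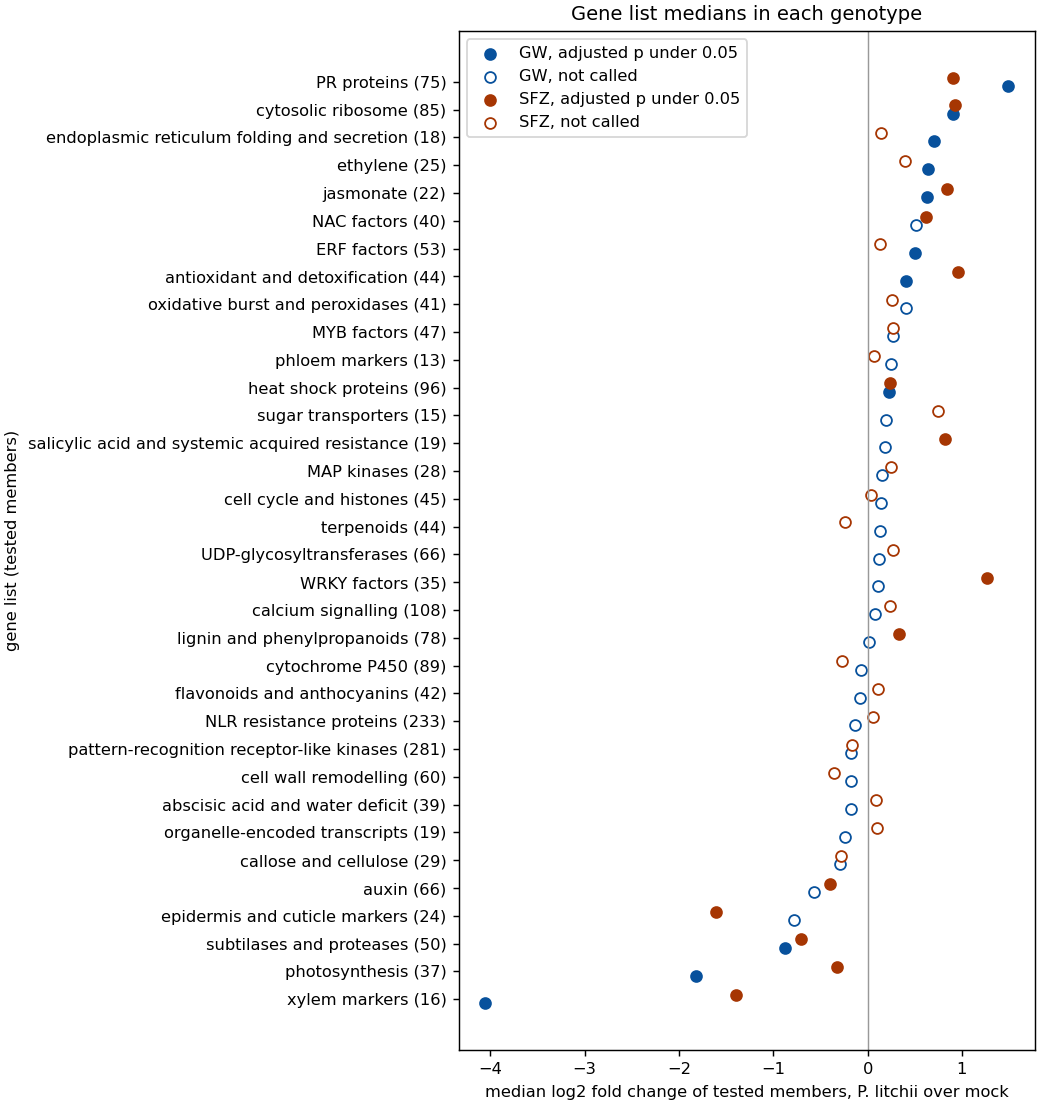
Median log2 fold change, P. litchii over mock, of 34 gene lists (vertical axis, tested members in brackets) in GW (blue) and SFZ (orange); filled points are lists with a camera adjusted p under 0.05 and open points are the others. The cytosolic ribosome median is 0.91 in GW and 0.92 in SFZ, and the photosynthesis median is -1.82 and -0.33.

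In SFZ leaves, a pathogenesis-related protein 1-like gene (LITCHI001382, chromosome 5, 26551517 to 26552424), of a class of secreted defence proteins, rose from 0.255 ± 0.106 to 405 ± 6.85 CPM (SD, n = 3), a log2 fold change of 10.58 ± 0.10 (SE, edgeR quasi-likelihood adjusted p = 1.10e-35). Its mock level was near 0, so this SE can understate the error of the fold. Phenylalanine ammonia-lyase (LITCHI018600, chromosome 15, 7262832 to 7266598), the entry enzyme of phenylpropanoid synthesis, rose from 3.09 ± 0.122 to 303 ± 4.66 CPM (log2 6.61 ± 0.07, edgeR adjusted p = 1.10e-34). A glutathione transferase (LITCHI018518, chromosome 15, 6360793 to 6369634) rose from 139 ± 3.3 to 1826 ± 26.9 CPM. The wax enzyme 3-ketoacyl-CoA synthase 6 (LITCHI005522, chromosome 14, 10863365 to 10866023) fell from 1302 ± 17.9 to 82.1 ± 0.76 CPM (log2 -3.99 ± 0.08, edgeR adjusted p = 2.51e-28). In all, 6492 genes rose and 6181 fell in SFZ (edgeR adjusted p under 0.05), with 2780 and 2598 changed at least 2-fold. With library totals as the only scaling 5282 rose and 7732 fell, and with no filter on low counts 6418 rose and 6900 fell.

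PR proteins gave 42 rises and 21 falls among 75 in SFZ, or 42 and 22 adjusted over the list alone, with a median of 0.91 (camera adjusted p = 0.00365, adjusted p = 0.143 with an estimated correlation). The thaumatin-like gene LITCHI009151 rose from 1.53 ± 0.253 to 1058 ± 20.2 CPM (n = 3). Of 44 antioxidant genes 32 rose and 5 fell, or 32 and 6 adjusted over the list alone, with a median of 0.96 (camera adjusted p = 8.58e-05, adjusted p = 0.111 with an estimated correlation), among them a parC-type glutathione transferase (LITCHI012577) from 10.2 ± 1.07 to 139.6 ± 5.08 CPM. Of 78 lignin and phenylpropanoid genes 40 rose and 23 fell, with a median of 0.33 (camera adjusted p = 0.0489, adjusted p = 0.0919 with an estimated correlation). Laccase 7 (LITCHI018291) rose from 0.116 ± 0.0811 to 679 ± 8.78 CPM, and CYP73A100 (LITCHI016493), a cinnamate hydroxylase, from 0 counts to 52.5 ± 3.31 CPM, at least 753-fold.

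WRKY factors gave 21 rises and 9 falls among 35 in SFZ, or 22 and 9 adjusted over the list alone, with a median of 1.26 (camera adjusted p = 0.00379, adjusted p = 0.0896 with an estimated correlation). WRKY 16 (LITCHI007728) rose by 5.99 ± 0.09 and WRKY 75 (LITCHI020315) by 3.95 ± 0.07 (log2, SE). Of 40 NAC factors 23 rose and 4 fell, with a median of 0.62 (camera adjusted p = 0.00814, adjusted p = 0.191 with an estimated correlation); NAC 100 (LITCHI019504) rose by 1.71 ± 0.04, while NAC 35 (LITCHI001130) fell by 4.24 ± 0.10. Of 19 genes of salicylic acid and systemic acquired resistance 14 rose and 4 fell, with a median of 0.83 (camera adjusted p = 0.00901, adjusted p = 0.116 with an estimated correlation). Salicylic acid-binding protein 2 (LITCHI006766), an esterase that releases salicylic acid, rose from 16.7 ± 0.51 to 219 ± 8.27 CPM, and calmodulin-binding protein 60 C (LITCHI004193) from 8.3 ± 0.632 to 105 ± 1.95 CPM (n = 3). Of 22 jasmonate genes 16 rose and 3 fell, with a median of 0.85 (camera adjusted p = 0.00365, adjusted p = 0.0629 with an estimated correlation). A 13S-lipoxygenase (LITCHI024090) rose from 3.6 ± 0.922 to 131 ± 1.52 CPM, and allene oxide synthase 3 (LITCHI001739) from 0 counts to 57.2 ± 2.47 CPM, at least 821-fold. The 13S-lipoxygenase LITCHI024086, of the same description, fell in SFZ as it did in GW. Its SFZ libraries ran from 41.3 to 43.9 CPM after mock and from 10.4 to 11.5 CPM after inoculation.

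The cytosolic ribosome list gave 77 rises and 1 fall among 85 in SFZ, with a median of 0.92 (camera adjusted p = 1.07e-15, adjusted p = 0.0896 with an estimated correlation). S4-3 (LITCHI018123) and L10 (LITCHI031025) rose by 1.24 ± 0.04 and 1.00 ± 0.04 (log2, SE). Of 96 heat shock genes 48 rose and 23 fell, with a median of 0.24 (camera adjusted p = 0.0236, adjusted p = 0.0629 with an estimated correlation), among them heat shock protein 83 (LITCHI009427), an Hsp90, from 26.1 ± 0.456 to 115 ± 1.17 CPM (n = 3).

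Epidermis and cuticle genes fell in SFZ, with 19 falls and 5 rises among 24 and a median of -1.61 (camera adjusted p = 9.65e-05, adjusted p = 0.0896 with an estimated correlation). Besides LITCHI005522, 3-ketoacyl-CoA synthase 11 (LITCHI014915) fell from 311 ± 3.83 to 15.2 ± 2 CPM (n = 3). Of 66 auxin genes 39 fell and 16 rose, or 40 and 16 adjusted over the list alone, with a median of -0.4 (camera adjusted p = 0.0217, adjusted p = 0.0629 with an estimated correlation). An ABP19a auxin-binding protein (LITCHI017544) fell from 535 ± 36.5 to 17.7 ± 1.54 CPM, while the organ-size regulator ARGOS (LITCHI015548) rose from 3.95 ± 0.548 to 189 ± 6.09 CPM. Xylem markers gave 12 falls and 1 rise among 16, with a median of -1.4 (camera adjusted p = 0.00588, adjusted p = 0.0629 with an estimated correlation). Proteases gave 26 falls and 11 rises among 50, with a median of -0.71, or -0.68 with bounds (camera adjusted p = 0.00712, adjusted p = 0.0629 with an estimated correlation), and SBT1.3 (LITCHI009223) fell by 5.57 ± 0.14. Photosynthesis genes split into 20 falls and 12 rises among 37, with a median of -0.33 (camera adjusted p = 0.0259, adjusted p = 0.375 with an estimated correlation). A chlorophyll a/b binding protein (LITCHI021457) fell from 1107 ± 34.5 to 73.6 ± 3.89 CPM, whereas Rubisco activase (LITCHI027700) rose from 124 ± 3.96 to 185 ± 3.63 CPM.

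The largest falls in SFZ included a GDSL esterase (LITCHI003288) from 41.5 ± 2.92 to 0.147 ± 0.0752 CPM (log2 -8.06 ± 0.21, n = 3) and a caffeoylshikimate esterase (LITCHI028666), which had 1 count after inoculation, a ratio of 367 (95% interval 65.8 to 14479). Phloem markers gave 6 rises and 3 falls among 13 (camera adjusted p = 0.62), guard cell markers 0 rises and 2 falls among 4, and organelle transcripts 5 rises and 7 falls among 19 (camera adjusted p = 0.618). With library totals only, the SFZ medians of heat shock and of lignin and phenylpropanoid genes were 0.09 and 0.19. With limma on log2(FPKM + 1) they were 0.09 and 0.16, with 0.24 for NAC factors, 0.54 for PR proteins, 0.60 for antioxidant genes, 0.47 for salicylic acid genes and -0.63 for xylem markers. For the other lists of this comparison that passed, the counts adjusted over the list alone equalled those over all genes. With the replicate number as a block the lignin and phenylpropanoid list did not pass (camera adjusted p = 0.0534), and no list kept its call with an estimated correlation.

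The responses of GW and SFZ overlapped. Across the 19088 tested genes their log2 fold changes correlated at 0.743 (Pearson) and 0.655 (Spearman), a relation across genes, which are not independent replicates. Both genotypes raised 4475 genes, where independent lists of these sizes would share 2118, and both lowered 4355, where independent lists would share 2336. The responses share no library. Of 10025 genes called in both, 88.1% moved the same way, 502 rose in GW and fell in SFZ, and 693 did the reverse. Genes raised in both included the thaumatin-like LITCHI009151, peroxidase A2 (LITCHI024182) and an ornithine decarboxylase-like gene (LITCHI010045), of polyamine synthesis, which had 0 counts in every mock library and was at least 637-fold higher in GW and at least 513-fold higher in SFZ.

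**Figure D3:**
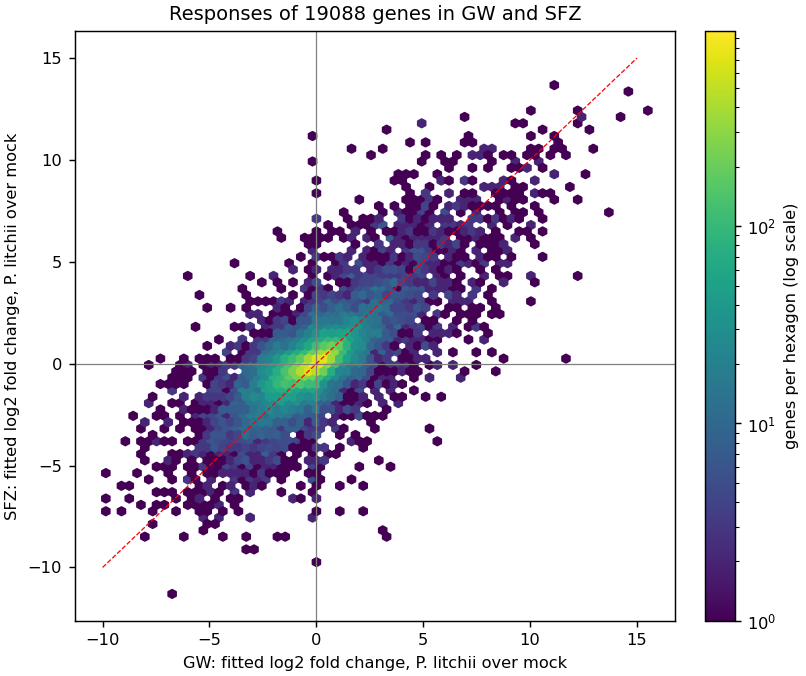
Fitted log2 fold change after P. litchii in SFZ (vertical) against GW (horizontal) for the 19088 tested genes; colour gives the number of genes per hexagon on a log scale, and the dashed line marks equal responses. Pearson's r across genes is 0.743.

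The difference between the responses is given as the interaction, the log2 response of SFZ minus that of GW. Rubisco activase (LITCHI027700) fell in GW and rose in SFZ, an interaction of 3.82 ± 0.06 (SE, n = 3 per group, edgeR quasi-likelihood adjusted p = 9.42e-29). Sedoheptulose-bisphosphatase (LITCHI027513, chromosome 3, 24535321 to 24539905), a Calvin cycle enzyme, fell from 116 ± 5.66 to 11.6 ± 0.642 CPM in GW and rose by a log2 of 0.46 ± 0.05 in SFZ (interaction 3.78 ± 0.08, edgeR adjusted p = 2.05e-25). In all, 8806 genes differed in response, 4986 with a higher and 3820 with a lower value in SFZ (edgeR adjusted p under 0.05), and 2255 and 1388 did so at least 2-fold. With library totals as the only scaling these were 6528 higher and 2870 lower. The balance turned to 4322 higher and 4455 lower with RLE factors, 3910 and 4121 with DESeq2, and 4213 and 4702 with no filter on low counts. Of the 8806, 4204 changed in the same direction in both genotypes, 2781 of them further in GW and 1423 further in SFZ. A further 1195 changed in opposite directions, 2077 passed in GW alone, 1253 in SFZ alone and 77 in neither.

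Of 37 photosynthesis genes 23 had a higher and 8 a lower response in SFZ, or 24 and 9 adjusted over the list alone, with a median of 1.06, or 0.89 with bounds (camera adjusted p = 0.00038, adjusted p = 0.375 with an estimated correlation). The antenna genes LITCHI021457 and LITCHI012016 went the other way, with interactions of -1.72 ± 0.06 and -0.30 ± 0.06. Xylem markers had a median of 2.05, or 1.66 with bounds, with 9 higher and 2 lower of 16 (camera adjusted p = 0.264), and organelle transcripts a median of 0.54, with 6 higher and 0 lower of 19 (camera adjusted p = 0.204). Of 18 folding genes 12 had a lower and 0 a higher response in SFZ, or 12 and 1 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.000377, adjusted p = 0.153 with an estimated correlation). A protein disulfide-isomerase (LITCHI011261), which forms disulfide bonds in secreted proteins, rose from 160.3 ± 4.46 to 242 ± 2.66 CPM in GW and fell from 213 ± 6.29 to 174 ± 3.28 CPM in SFZ (n = 3).

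Salicylic acid genes had the higher response in SFZ for 11 of 19 and the lower for 2, the same counts adjusted over the list alone, with a median of 0.7, or 0.73 with bounds (camera adjusted p = 0.0189, adjusted p = 0.343 with an estimated correlation). In mock leaves 4 of them were higher and 10 lower in SFZ (median -0.33, camera adjusted p = 0.536), and in inoculated leaves 9 higher and 4 lower (camera adjusted p = 0.682). The resistance regulator EDS1 (LITCHI022281) rose by 1.09 ± 0.05 in SFZ and by 0.24 ± 0.05 in GW (log2, SE, n = 3 per group), an interaction of 0.85 ± 0.07. Of 41 peroxidases and NADPH oxidases 18 had a lower and 8 a higher response in SFZ, or 19 and 8 adjusted over the list alone, with a median of -0.89, or -0.87 with bounds (camera adjusted p = 0.026, adjusted p = 0.343 with an estimated correlation). A lignin-forming peroxidase (LITCHI011382) rose from 2.67 ± 0.332 to 449.8 ± 3.86 CPM in GW and from 58.5 ± 6.18 to 548 ± 10.2 CPM in SFZ. Epidermis and cuticle genes gave 11 lower and 6 higher of 24, or 11 and 8 adjusted over the list alone, with a median of -0.59 (camera adjusted p = 0.0313, adjusted p = 0.418 with an estimated correlation). The hydroxylase CYP86A8 (LITCHI025730), of cutin synthesis, fell in GW and rose in SFZ (interaction 3.02 ± 0.13), and 3-ketoacyl-CoA synthase 6 (LITCHI005522) fell further in SFZ (-1.85 ± 0.10). In mock leaves 7 folding genes were higher and 5 lower in SFZ (camera adjusted p = 0.771), as were 16 and 11 of the peroxidases and NADPH oxidases (0.771) and 13 and 9 of the epidermis genes (0.764). Cytosolic ribosome genes had a median of -0.08, with 22 lower and 11 higher, a balance that turned to 10 and 21 with library totals only (camera adjusted p = 0.204).

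Among single genes, the 13S-lipoxygenase LITCHI024090 (chromosome 13, 11227617 to 11236613) was at 39 ± 5.21 CPM in mock and 36.2 ± 5.49 CPM in inoculated GW leaves and rose in SFZ, an interaction of 5.29 ± 0.16 (edgeR adjusted p = 2.43e-22). A probable mannitol dehydrogenase (LITCHI007195) rose from 2 counts to 87.1 ± 3.32 CPM in SFZ, a ratio of 1874 (95% interval 519 to 15479), against 0.467 ± 0.175 to 1.64 ± 0.041 CPM in GW (n = 3). An adenylate isopentenyltransferase (LITCHI014695), of cytokinin synthesis, fell by 3.46 ± 0.13 in GW and rose by 3.77 ± 0.34 in SFZ (log2, SE). MYB41 (LITCHI013257), a cuticle-related transcription factor, rose from 0 counts to 45.9 ± 3.16 CPM in GW, at least 595-fold, and from 0.349 ± 0.211 to 6.93 ± 0.992 CPM in SFZ. An epidermis-specific secreted glycoprotein gene (LITCHI012883, chromosome 2, 21470147 to 21472120) had 0 counts in mock GW and 35.0 ± 1.87 CPM in inoculated GW, at least 454-fold higher, against 27.5 ± 2.8 and 31.6 ± 3.08 CPM in SFZ (edgeR interaction adjusted p = 7.55e-20). With limma on log2(FPKM + 1) the interaction medians were -0.25 for peroxidases and NADPH oxidases and 0.47 for xylem markers, and without GW mock replicate 3 that of organelle transcripts was 0.33. No list of the interaction kept its call with an estimated correlation.

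**Figure D4:**
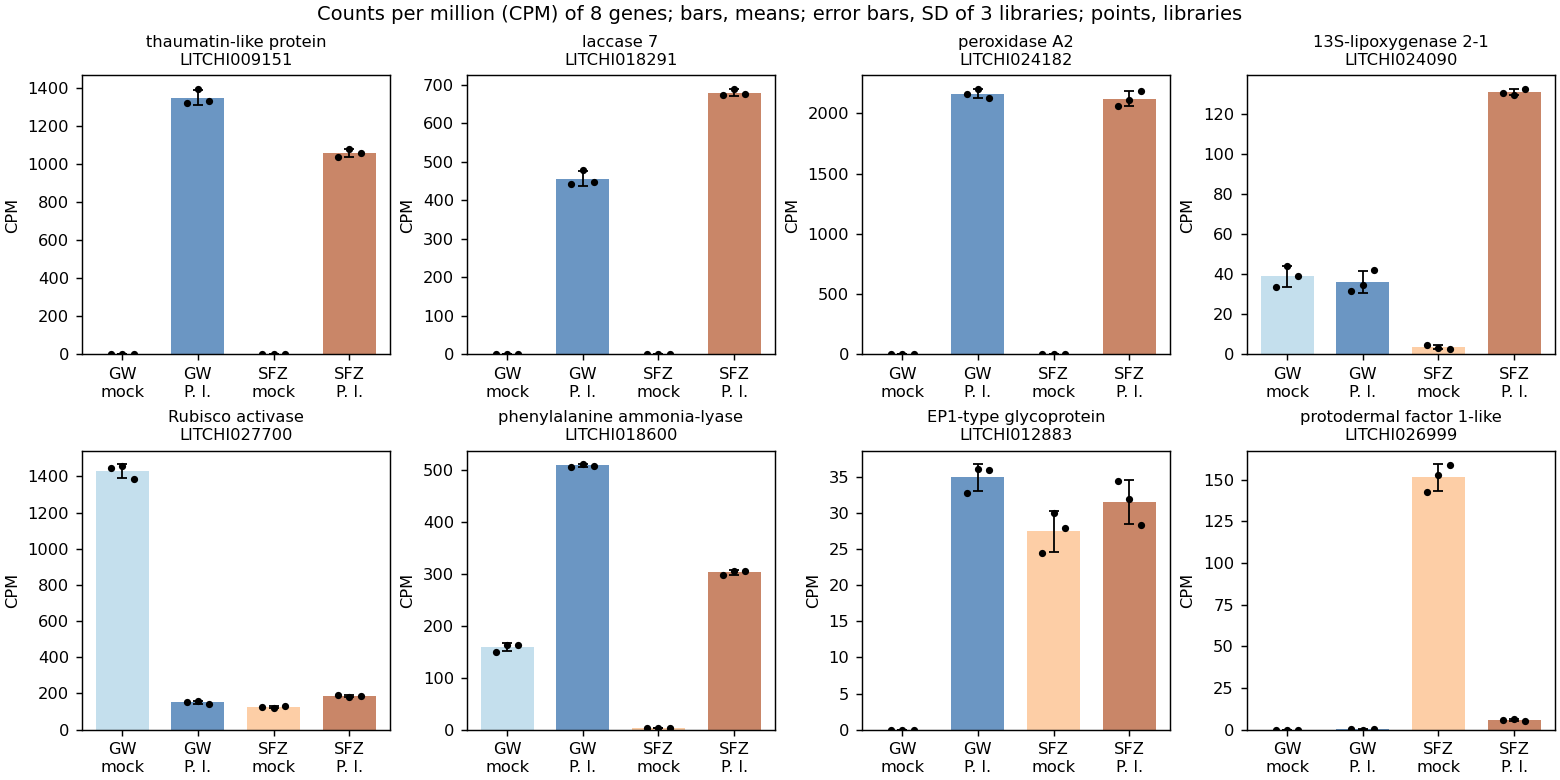
CPM of 8 named genes in the 4 groups; bars are means, error bars SD (n = 3) and points single libraries. Rubisco activase (LITCHI027700) is at 1429.6 CPM in mock GW and at most 185 CPM in the other groups.

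Between mock-treated leaves of the genotypes, single genes differed by large folds, while no gene list passed. A protodermal factor 1-like gene (LITCHI026999, chromosome 3, 15790273 to 15792962), of a family expressed in the outer cell layer, had 0 counts in mock GW and 151 ± 8.11 CPM in mock SFZ (SD, n = 3), at least 1964-fold higher. A probable disease resistance protein (LITCHI013515, chromosome 2, 31167325 to 31171280) had 0 counts in every GW library and 72.3 ± 3.06 CPM in mock SFZ, at least 938-fold higher. Such folds need not reflect regulation, since the gene may be absent in GW or differ there from the reference sequence. Phenylalanine ammonia-lyase (LITCHI018600) stood at 159 ± 8.01 CPM in mock GW and 3.09 ± 0.122 CPM in mock SFZ (log2 -5.69 ± 0.07, edgeR quasi-likelihood adjusted p = 3.07e-32). Rubisco activase (LITCHI027700) was lower in mock SFZ by a log2 of -3.52 ± 0.04. In all, 6732 genes were higher and 7140 lower in SFZ (edgeR adjusted p under 0.05), with 3620 and 3041 at least 2-fold apart. The balance turned to 7679 higher and 6151 lower with library totals only, 6934 and 6897 with RLE factors, 6936 and 6787 with DESeq2, and 7765 and 7199 with no filter on low counts.

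Other genes with 0 counts in mock GW were the AP-4 complex subunit mu (LITCHI003532), at least 470-fold higher in SFZ, a glutamate receptor 2.7-like gene (LITCHI013034), at least 406-fold, and a disease resistance protein (LITCHI004530), at least 392-fold. Genes with 0 counts in mock SFZ were an alkenal reductase (LITCHI015761), at least 735-fold lower, an auxin response factor 1 gene (LITCHI000399), at least 481-fold, a zinc finger BED gene (LITCHI000400), at least 384-fold, the F-box gene CPR1 (LITCHI030082), at least 133-fold, and a disease resistance protein (LITCHI013138), at least 132-fold. All these genes, and LITCHI026999 and LITCHI013515 above, had at most 3 counts in all libraries of the other genotype. Absent genes, silenced genes and sequence differences stay open for them, as the closing section says. Of 233 NLR genes, the intracellular immune receptors, 102 were higher and 89 lower in SFZ (camera adjusted p = 0.771). WRKY factors were higher for 11 and lower for 21 of 35 (camera adjusted p = 0.536), and photosynthesis genes for 11 and 18 of 37 (camera adjusted p = 0.764). Camera called 0 lists here, with 1 list at an unadjusted p under 0.05 and 0 with an estimated correlation, while fry, which asks whether a list's genes moved on balance, called 29.

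Between inoculated leaves of the genotypes, single genes differed while no gene list passed. Peroxidase A2 (LITCHI024182) reached 2163 ± 38.3 CPM in GW and 2121 ± 61.9 CPM in SFZ (SD, n = 3), a log2 difference of -0.03 ± 0.04 (SE, edgeR quasi-likelihood adjusted p = 0.56). The PR 1-like gene LITCHI001382 was higher in SFZ by 1.62 ± 0.05 and the glutathione transferase LITCHI018518 by 1.80 ± 0.05, whereas the kinase CIPK2 (LITCHI027467) was lower by a log2 of -3.07 ± 0.05. In all, 7436 genes were higher and 6635 lower in inoculated SFZ than in inoculated GW (edgeR adjusted p under 0.05), with 4086 and 2536 at least 2-fold apart, and 9572 and 4779 with library totals as the only scaling. With RLE factors 6987 were higher and 7079 lower. Of 233 NLR genes 64 were lower, 46 did not pass and the rest were higher, with a median of 0.76, or 0.38 with limma on log2(FPKM + 1), and of 37 photosynthesis genes 24 were higher and 10 lower. The camera adjusted p was above 0.1 for both. Folding genes were higher for 3 and lower for 13 of 18 (camera adjusted p = 0.106), and organelle transcripts higher for 15 and lower for 1 of 19 (camera adjusted p = 0.193). Camera called 0 lists, with 5 at an unadjusted p under 0.05 and 1 with an estimated correlation, and fry called 31.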

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

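The comparison of photosynthesis with other lists below, and library totals as the only scaling, were chosen only after the results were seen. Each result in this part was picked out because the response to P. litchii differed between SFZ and GW in the edgeR interaction or in camera on it. This held for 8806 genes, for 5 gene lists, and for 65 of the 93 named genes of the responses and the interaction.

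As a list, photosynthesis genes fell further in GW than in SFZ, with an interaction median of 1.06 over 37 genes (quartiles 0.07 to 1.88, camera adjusted p = 0.00038, adjusted p = 0.375 with an estimated correlation). Not all members did so, and the antenna genes LITCHI021457 and LITCHI012016 fell further in SFZ. Scaling does not account for the list median, since it was 0.98 with RLE factors and 1.21 with library totals only. A uniform loss of leaf transcripts in inoculated GW leaves would be removed by scaling to a common total. Other lists therefore cannot test it. The cytosolic ribosome median was -0.0791, where dilution was predicted to give about that of photosynthesis, but this list rose in both genotypes. Phloem was at -0.06 and epidermis at -0.59, while xylem at 2.05 and organelle transcripts at 0.54 had the sign of photosynthesis. These values leave dilution undecided. A genotype difference in how far photosynthesis genes are lowered could account for the result and was not tested apart from it. Clock genes also differed between the groups, as given further below. Sampling at different times of day was not tested as a cause of the photosynthesis result and stays open. Between the mock groups the list had a median of -0.11, with 11 genes higher and 18 lower in SFZ (camera adjusted p = 0.764), and the median turned above 0 with library totals only and with limma.

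The other lists were folding in the endoplasmic reticulum (camera adjusted p = 0.000377), salicylic acid (0.0189), peroxidases and NADPH oxidases (0.026) and epidermis and cuticle (0.0313). With an estimated correlation their adjusted p were 0.153, 0.343, 0.343 and 0.418. Beside the 8806 genes, 2 of 100 splits of the libraries gave as many, the real one included, and the highest other gave 14129. That split exchanges all mock and inoculated labels of SFZ, so it adds the responses where the real one subtracts them, which is a structure of the samples. The splits move the responses themselves, so they do not decide whether chance can be excluded for this count.

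The values below are interactions, the log2 response of SFZ minus that of GW, with SE and n = 3 per group. Among defence proteins they were for the thaumatin-like gene (LITCHI009151, -1.59 ± 0.24), peroxidase A2 (LITCHI024182, -1.03 ± 0.16), the P2 protein (LITCHI003626, -3.76 ± 0.07), the PR 1-like gene (LITCHI001382, 2.38 ± 0.43), the lignin-forming peroxidase (LITCHI011382, -4.16 ± 0.11) and a pericarp peroxidase (LITCHI006553, 2.37 ± 0.09). Unequal mock levels can give such values. The P2 protein ran from 20.7 to 24.1 CPM in mock GW and 311 to 360 CPM in mock SFZ, and after inoculation from 2484 to 2588 and 2745 to 2871 CPM. The PR 1-like gene was low in both mock groups. Phenylalanine ammonia-lyase had the value (LITCHI018600, 4.94 ± 0.09). It ran from 150 to 164 CPM in mock GW and 3.01 to 3.23 CPM in mock SFZ. After inoculation it stayed higher in GW, at 507 to 513 against 298 to 306 CPM. A 13S-lipoxygenase had (LITCHI024090, 5.29 ± 0.16), against a lipoxygenase (LITCHI004066, -0.68 ± 0.07). Ethylene genes included an aminocyclopropane-carboxylate synthase (LITCHI022037, -1.36 ± 0.17), ethylene receptor 2 (LITCHI015371, -2.21 ± 0.06) and RAP2-3 (LITCHI014444, -2.51 ± 0.07).

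Transcription factors were WRKY 75 (LITCHI020315, -1.83 ± 0.17), WRKY 16 (LITCHI007728, 2.32 ± 0.14), NAC 72 (LITCHI013207, -1.10 ± 0.05), NAC 35 (LITCHI001130, -0.71 ± 0.16) and NAC 100 (LITCHI019504, -0.20 ± 0.06). Salicylic acid genes were binding protein 2 (LITCHI006766, 0.70 ± 0.10), calmodulin-binding protein 60 C (LITCHI004193, 1.61 ± 0.13) and EDS1 (LITCHI022281, 0.85 ± 0.07). Glutathione transferases spread on both sides (LITCHI023121, -1.22 ± 0.10; LITCHI020167, -0.21 ± 0.06; LITCHI018518, 1.78 ± 0.07; and the parC type, LITCHI012577, 4.14 ± 0.18). Chaperones and folding genes were an HSP20-like gene (LITCHI023051, -2.04 ± 0.20), the dnaJ protein 8 (LITCHI031806, -1.63 ± 0.05), heat shock protein 83 (LITCHI009427, 1.71 ± 0.07), Sec61 gamma (LITCHI020758, -0.75 ± 0.07) and a protein disulfide-isomerase (LITCHI011261, -0.89 ± 0.06). Ribosomal proteins differed little, with S4-3 (LITCHI018123, -0.19 ± 0.06) and L10 (LITCHI031025, -0.16 ± 0.05).

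Photosynthesis genes were Rubisco activase (LITCHI027700, 3.82 ± 0.06), sedoheptulose-bisphosphatase (LITCHI027513, 3.78 ± 0.08), CP26 (LITCHI012016, -0.30 ± 0.06), a chlorophyll a/b binding protein (LITCHI021457, -1.72 ± 0.06) and nuclear psbY (LITCHI004785, 1.41 ± 0.06). Wall genes were CesA7 (LITCHI016041, 2.26 ± 0.31), IRX14H (LITCHI006932, -0.65 ± 0.07) and a xyloglucan transferase (LITCHI016359, 0.65 ± 0.10). Cuticle genes were the ketoacyl-CoA synthases 6 (LITCHI005522, -1.85 ± 0.10), 11 (LITCHI014915, -0.90 ± 0.20) and 10 (LITCHI017426, 0.34 ± 0.08) and CYP86A8 (LITCHI025730, 3.02 ± 0.13). Proteases were SBT1.3 (LITCHI009223, -1.62 ± 0.26), SBT1.1 (LITCHI012194, 3.44 ± 0.62), an aspartyl protease (LITCHI006406, 4.22 ± 0.74) and PCS1 (LITCHI008108, -2.80 ± 0.42). Other genes were CIPK2 (LITCHI027467, -3.85 ± 0.09), sugar transport protein 13 (LITCHI014765, -2.52 ± 0.08), ARGOS (LITCHI015548, 1.16 ± 0.14), ABP19a (LITCHI017544, -3.97 ± 0.09), an isopentenyltransferase (LITCHI014695, 7.23 ± 0.34) and a GDSL esterase (LITCHI003288, -11.12 ± 0.53).

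For 12 genes a group had 3 or fewer counts, so the edgeR interaction is given by its p alone. These were a mannitol dehydrogenase (LITCHI007195, adjusted p = 1.34e-11), the EP1 glycoprotein (LITCHI012883, adjusted p = 7.55e-20), an NDR1/HIN1-like gene (LITCHI010464, adjusted p = 4.29e-08), a DJ-1 homolog (LITCHI008114, adjusted p = 2.00e-07), a metalloendoproteinase (LITCHI002640, adjusted p = 3.97e-07) and MYB41 (LITCHI013257, adjusted p = 4.23e-07). The others were a parA-type glutathione transferase (LITCHI031059, adjusted p = 7.97e-07), a berberine bridge enzyme-like gene (LITCHI023024, adjusted p = 4.78e-06), the protodermal factor 1-like gene (LITCHI026999, adjusted p = 0.00105), a caffeoylshikimate esterase (LITCHI028666, adjusted p = 0.00947), a GDSL esterase (LITCHI016421, adjusted p = 0.0206) and a galactose-1-phosphate uridyltransferase (LITCHI010598, adjusted p = 0.042).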

How the results depend on the processing

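Library totals as the only scaling was chosen only after the data were seen. With a log2 fold change of at least 1 the counts were 6516 genes in GW, 5378 in SFZ, 3643 in the interaction, 6661 between mock groups and 6622 between inoculated groups, fewer by construction. The correlation of the responses was 0.646 with DESeq2, 0.613 with no filter on low counts, and 0.725 to 0.734 with each library left out, and the cause was not tested. Leaving out each library gave 12981 to 13542 genes in GW, 12019 to 13020 in SFZ, 8256 to 8842 in the interaction, 13388 to 14203 between mock groups and 13607 to 14439 between inoculated groups. With the replicate block the counts were 13343, 12517, 8653, 13755 and 13984, and 169 of 170 list tests kept their call. Libraries that share a number correlated at -0.245 to 0.141 over 10400 genes, so the number gave no sign of pairing. With an estimated correlation 140 of 170 list tests were unchanged and 30 were no longer called. The 112 results on named genes kept direction and call in up to 21 alternatives each. These genes were chosen from the same data for large folds or small p, so this says little about other calls. The balance of higher and lower calls turned under some setting in every comparison, and the heat shock list in GW turned from 47 rises and 21 falls to 32 and 38 with library totals only.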

Other observations

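The family tests, the random draws for clock genes, the NLR test, the replicate 1 test and the overlap counts of this part were chosen only after results had been seen. Genes were also grouped by the leading words of their descriptions into 124 families of at least 10 tested genes. Family medians use fitted fold changes without the bounds for groups at 0 counts, so large medians may be overstated. Chitinases, which break down chitin, rose for 10 of 11 genes in GW with a median log2 fold change of 4.89 (camera adjusted p = 3.49e-05, adjusted p = 0.327 with an estimated correlation). In SFZ they rose for 10 of 11 with a median of 9.06 (camera adjusted p = 1.75e-06, adjusted p = 0.292 with an estimated correlation), and in mock leaves 8 were lower and 1 higher in SFZ (median -3.15, camera adjusted p = 0.016, adjusted p = 0.616 with an estimated correlation). Their response was higher in SFZ for 7 and lower for 0, with a median of 2.26 (camera adjusted p = 0.179). Of 10 thaumatin genes 9 were higher and 0 lower in mock SFZ (median 1.74, camera adjusted p = 0.0267, adjusted p = 0.408 with an estimated correlation), and their response was lower in SFZ for 7 and higher for 0 (camera adjusted p = 0.00123, adjusted p = 0.15 with an estimated correlation). Histones, which package DNA, rose for 13 of 16 in GW and fell for 2 (median 0.92, camera adjusted p = 0.00304, adjusted p = 0.39 with an estimated correlation), and in SFZ 10 rose and 3 fell (camera adjusted p = 0.189). Their interaction was lower for 9 and higher for 0, with a median of -0.40, or -0.25 with library totals only (camera adjusted p = 0.0067, adjusted p = 0.579 with an estimated correlation). In inoculated leaves 13 were lower and 2 higher in SFZ, with a median of -0.64, or -0.38 with library totals only (camera adjusted p = 0.00794, adjusted p = 0.596 with an estimated correlation). The wider list of dividing-cell genes gave 16 rises and 13 falls among 45 in GW (camera adjusted p = 0.502), which turned to 13 and 18 with library totals only, and 21 and 12 in SFZ (camera adjusted p = 0.514).

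Pentatricopeptide repeat proteins, which process RNA in organelles, differed between the genotypes under both treatments. Of 349 tested, 194 were higher and 52 lower in mock SFZ than in mock GW, with a median of 0.56 (camera adjusted p = 0.016, adjusted p = 0.0052 with an estimated correlation). In inoculated leaves 235 were higher and 41 lower, with a median of 0.92 (camera adjusted p = 4.70e-05, adjusted p = 0.000644 with an estimated correlation). With library totals only the medians were 0.67 and 1.18 (n = 3 per group). Disease resistance proteins of inoculated leaves were higher in SFZ for 94 and lower for 37 of 167, with a median of 0.88 (camera adjusted p = 0.0415, adjusted p = 0.525 with an estimated correlation). Genes with a count numbered 20589 to 21368 in GW libraries and 21901 to 22182 in SFZ libraries. Sequence differences of the genotypes from the reference were not tested, so these family differences need not reflect expression. Organelle transcripts were higher for 9 and lower for 3 of 19 in mock SFZ (camera adjusted p = 0.771).

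A hypothesis was that the mock leaves of the genotypes were sampled at different times of day. Late elongated hypocotyl (LITCHI026770), a morning gene of the clock, was at 246 CPM in mock GW and 2.62 CPM in mock SFZ, and gigantea (LITCHI011520), an evening gene, at 104 and 2127 CPM (means, n = 3). The 8 other morning genes had a median of -1.82 between mock groups and 5 evening genes 0.04, a difference of 1.86 that 0.2% of 10000 random draws reached. Of these morning genes 7 were lower and 1 higher in mock SFZ, and of the evening genes 2 were higher and 0 lower. The same difference was 2.12 between inoculated groups, 1.35 between inoculated and mock leaves in GW and 1.80 in SFZ. Evening genes gave 3 rises and 1 fall in GW and 2 rises and 2 falls in SFZ. In SFZ their median was -0.17, so the difference there came from the morning genes. Different sampling times could account for the differences between genotypes and within each, and so could a genotype difference in the clock or an effect of P. litchii on it, and all stay open because the labels give no time of day.

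Another pattern was genes detected in 1 genotype, of which 131 had at least 5 CPM there and at most 3 counts in the other (24 in GW, 107 in SFZ, of 13590 candidates), and NLR genes made up 8 of the 131 and 129 of the candidates (Fisher's exact test odds ratio 7.17, p = 3.45e-05). That test treats genes as independent. Yet LITCHI004530, LITCHI004531 and LITCHI004540, detected in SFZ, lie between 1877464 and 1960313 on chromosome 14, so the p may be too small. Counts near the detection limit were predicted to show as a median under 10 CPM, and the median was 8.84 CPM, but the selection at 5 CPM shapes this value, so it decides nothing. Of 140 genes picked with the replicate 1 libraries alone 100% kept a difference of at least 10-fold in replicates 2 and 3, so the differences recurred between libraries. The minimum of 5 CPM largely assured this result. It is therefore no separate test of counting noise, and the replicates may be technical. Of the 131 genes 13.7% lay next to another of the same direction, against at most 7.63% in 10000 random draws, as sequence or presence differences against the reference could give. The draws also treat genes as independent. Yet some neighbours lie close together, such as LITCHI022659, ending at 7981957 on chromosome 10, and LITCHI022660, starting at 7982171. The excess may therefore be overstated. Sequence differences, absent genes and silenced genes stay open, since no genome was given.

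A further hypothesis was that mock SFZ leaves already carried part of the GW response. The test written for it, a covariance of the GW response with the mock difference above that of simulated data, was met (0.327 against 0.0206). The correlation was 0.134, and its median in simulated data was 0.485. The simulated data held no differences between groups, so the shared mock GW libraries alone set that median. Setting these correlations side by side therefore decides nothing. Of genes raised in GW 2039 were higher in mock SFZ, where independent lists would share 2196, and 2374 were lower. Of genes lowered in GW 3306 were lower in mock SFZ, where independent lists would share 2699, and 2128 were higher. Both lists of each overlap use the mock GW libraries, and noise in those libraries would raise both overlaps. At the spread between replicates, such noise gave a median covariance of only 0.0196 in simulated data, against the 0.327 observed. Its share in the excess among lowered genes was not measured, and it would not give the shortfall among raised genes. No overlap was simulated, so these counts do not decide the hypothesis. A mock GW group that stood apart from the other groups could give the covariance as well, so the hypothesis stays open.

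Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. In GW 1 of 10 splits, the real one, reached 13442 genes and the highest other gave 1. In SFZ the real split gave 12673 and was the only 1 to do so, with 0 in the highest other. Between mock groups the real split gave 13872, again 1 of 10, with 0 in the highest other, and between inoculated groups 14071, 1 of 10, with 0.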
